A study of Mus musculus with 2 samples.

How the data were processed

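The series holds 2 microarrays of mouse CD4+ T cells, 1 from an untreated culture and 1 from a culture given 25 ng/ml of recombinant murine IL-27. Per the labels' protocols, naive CD4+ T cells came from the spleen and lymph nodes of female C57BL/6J mice, were activated for 60 h on plates coated with antibodies to CD3 and CD28, and 100 ng of total RNA was amplified and biotin-labelled with a 3' in vitro transcription kit. Such a kit copies RNA from its poly(A) end, and each gene is read by 1 or more probe sets, groups of short probes placed mostly near the 3' end of the transcript.

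The deposited table gives 1 intensity per probe set and array on a linear scale. Per the submitters' processing notes the intensities were made with RMA, which subtracts background, quantile-normalizes the arrays and summarizes each probe set, and the version and settings are not given in the sources used here. RMA forces the intensity distributions of arrays processed together to be nearly alike, so a change in total RNA per cell cannot be seen, and it compresses differences of dim probe sets. The table has no detection calls. Median intensities of 33.3 on the array labelled untreated and 32.4 on the array labelled IL-27-treated, and means of 334.8 and 335.0, were close. Each group has 1 array, so there are no biological or technical replicates, no test was run and no p-value or standard error is given. The number of arrays limits the precision of every difference.

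Of the 22716 probe sets, 18003 had 1 gene symbol in the platform annotation, 287 had several and 4426 had none listed, among them the 90 Affymetrix control probe sets. Only probe sets with 1 symbol were used for genes. Entrez gene identifiers of 17977 of them were found in a RefSeq gene table of assembly GRCm38.p6, which changed 0 symbols and served for names alone. No chromosome positions are given, because the array table names no genome build.

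Intensities were converted to log2 without a pseudocount and without further normalization, and a difference is always the array labelled IL-27-treated minus the array labelled untreated. A gene was represented by the probe set with the highest mean log2 level, which gave 11807 genes. A background floor was set at the 95th percentile of the levels of genes of other tissues (liver, pancreas, heart, brain, testis and others), of which 39 of 46 were measured. The floor was an intensity of 24.1, or 4.59 on the log2 scale, and 6920 genes (58.6%) exceeded it on at least 1 array. A gene counted as higher or lower when its measured values were at least 2-fold apart, and where raising dim values to the floor changed a list's count, that count is given too. Where a gene was below the floor on the dimmer array, its fold is given as a lower bound, the brighter intensity over the floor, and no fold is given for a gene below it on both.

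The genes named were set by a rule with 4 parts: the 12 genes with the largest positive and the 12 with the largest negative difference, transcription factors at least 2-fold apart (up to 12 per direction), up to 4 members of each gene list with the largest absolute difference, and 27 genes of IL-27 signalling and T cell differentiation, of which 24 were analysed here. Genes named outside this rule were chosen after their values were seen and are marked as such. In all, 31 gene lists were fixed: 30 of symbols, including the off-tissue list, and 1 of transcription factors drawn by symbol patterns. Of these, 1 list is not reported here. The patterns also take a few cofactors, such as Pou2af1 and Irf2bp1. Members of a list can belong to others as well, so the lists are not independent.

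For each list with at least 3 members above the floor, the median difference was placed among 10000 random lists of the same size, drawn from the same 20 bins of mean level. The percentile describes these 2 arrays and is not a p-value. A list was called set apart at or below percentile 2.5 or at or above percentile 97.5.

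The comparison, the threshold, the floor, the lists, the naming rule and all but 1 of the alternatives were set before the data were examined. The percentile limits that set a list apart, the minimum of 3 members, the 20 bins, the alternative that raises dim values to the floor, the gene families of the closing section and all tests of explanations were chosen after seeing the data. Alternatives covered the filter on dim probe sets, normalization between the arrays, the choice of probe set, the fold threshold and a pseudocount of 16. The mean of a gene's probe sets also takes in those below the floor on both arrays.

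Agreement among probe sets of 1 gene gave the only internal measure of technical error. It covers probe-level error only, not variation between cultures or hybridizations.

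The procedure was tested on simulated arrays built from each probe set's mean level over the 2 real arrays. The noise SD of a log2 difference was 0.2, and 6797 simulated genes lay above the floor. Of 100 genes raised by 1.5 log2 units 99% were recovered, and of 100 lowered by as much 100% were. Of 20 lists of 12 genes given a shift of 0.3, 18 were called set apart, with a mean recovered median of 0.30. Of 100 unshifted lists 4 were. These were random lists placed among other random lists, so a low count was fixed in advance. The altered genes and the list members were drawn only from genes with a mean level well above the floor. All had the same noise, small against a shift of 1.5, so high recovery was built in. Measured differences of genes above background were wider than this noise, with quartiles of -0.20 and 0.22. The 18 of 20 lists may thus overstate what would be recovered from the real arrays. Recovery of genes near the floor was not tested. Calculations used Python 3.11.15 with numpy 2.4.6 and pandas 2.3.3, and plots matplotlib 3.10.9.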

Results

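Gene expression was measured in CD4+ T cells activated for 60 h through the T cell receptor and CD28, without or with 25 ng/ml of IL-27. IL-27 is a cytokine of the IL-12 family that signals through the receptor chains Il27ra and Il6st, in part by the transcription factor STAT3. There was 1 array per group and thus no replicate. The values below describe 2 arrays and cannot separate an effect of the cytokine from the variation between cultures. Both arrays covered 11807 genes, 6920 of them above background on at least 1 array, and their log2 levels correlated across all probe sets with a Pearson r of 0.989, where probe sets are not independent replicates.

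The comparison asked which genes, and above all which transcription factors, IL-27 induces. Of the genes above background, 103 were at least 2-fold higher and 189 at least 2-fold lower on the array labelled IL-27-treated. Among the higher genes were Lad1, Tnfsf11, the T-box factor Eomes and Il2, and among the lower ones Plac8, Il21, Socs3 and Prdm1. Directions follow the labels throughout. Several genes that IL-27 is known to raise by STAT3, such as Socs3, Il10, Il21 and Prdm1, were lower on the array labelled IL-27-treated, and Il2 and Gata3, which it is known to restrain, were higher there.

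The middle 50% of genes above background, between the quartiles, differed by -0.20 to 0.22 on the log2 scale, with a median of 0.02. Of the genes called higher, 24 were below the floor on the array labelled untreated, and 48 of those called lower were below it on the array labelled IL-27-treated. With dim values raised to the floor, 94 genes were at least 2-fold higher and 169 lower.

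Lad1, which encodes an anchoring filament protein, had intensities of 40.4 on the array labelled untreated and 691.8 on the array labelled IL-27-treated, a 17.1-fold difference. Tnfsf11, the cytokine RANKL, was 10.3-fold higher, with differences of 2.76 and 3.36 from its 2 probe sets. Penk, the precursor of enkephalin peptides, was 7.50-fold higher and the interferon-inducible GTPase gene Iigp1 6.65-fold higher. Trat1, an adaptor of the T cell receptor, was 6.20-fold higher, and Phlda1 and Ifi205 were higher by 2.80 and 2.78 on the log2 scale. Tnfsf11 and Phlda1 were close to the floor on the array labelled untreated, at intensities of 27.5 and 25.6. Ifi205 belongs to a cluster of near-identical genes whose probe sets can cross-hybridize. A further 4 of the 12 genes with the largest positive differences were below the floor on the array labelled untreated. These were Cd83, a marker of activated lymphocytes and dendritic cells, at least 14.1-fold higher, Csf2, which encodes GM-CSF, at least 6.46-fold, the TNF family ligand Cd70 at least 3.96-fold and the protease gene Capn3 at least 3.04-fold.

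Among the 12 genes with the largest negative differences, 4 were above background on both arrays. Plac8 had intensities of 1875 and 100.6 and was thus 18.6-fold lower on the array labelled IL-27-treated. Ctla2a, an inhibitor of cysteine proteases, was 15.0-fold lower, the class I gene H2-Q10 14.6-fold lower and the cytokine gene Il21 14.4-fold lower. Probe sets of Ctla2a and Ctla2b, and of H2-Q10 and other class I genes, can pick up related transcripts, so these values are uncertain. The other 8 were below the floor on the array labelled IL-27-treated and have no order among themselves. The serpin gene Serpinb5 was at least 34.5-fold lower, Lilrb4a, an inhibitory receptor with close relatives, at least 24.6-fold, Serpinb1a at least 17.6-fold by 1 of its 2 probe sets and the GTPase gene Gem at least 14.3-fold. Serpinf1 was at least 13.4-fold lower, and at least 2.77-fold by its dimmer probe set, the cytokine gene Tgfb3 at least 13.3-fold, the protease inhibitor Timp1 at least 7.60-fold and Ctla2b at least 6.80-fold.

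**Figure D1:**
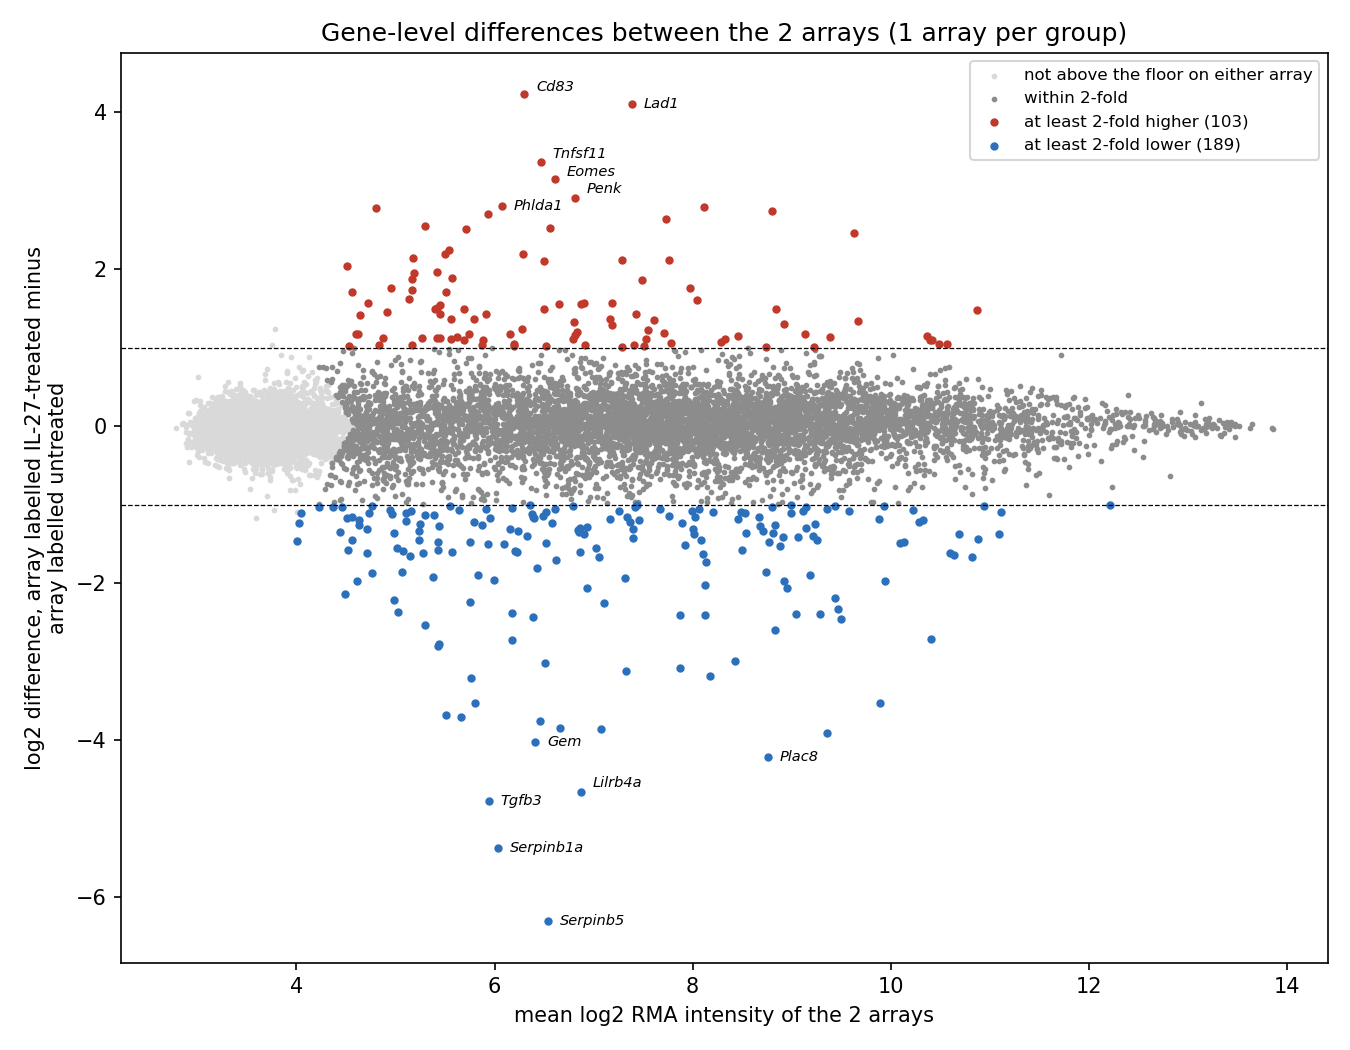
Each point is a gene, with its mean log2 RMA intensity over the 2 arrays on the horizontal axis and the log2 difference, array labelled IL-27-treated minus array labelled untreated, on the vertical axis. Red marks the 103 genes at least 2-fold higher and blue the 189 at least 2-fold lower among genes above the background floor, pale grey marks genes below the floor on both arrays, dashed lines mark 2-fold, and the 6 genes with the largest difference in each direction are named by their measured values.

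Among transcription factors, the object of the screen, 3 were at least 2-fold higher and 10 at least 2-fold lower on the array labelled IL-27-treated, out of 221 above background and 499 measured. Eomes, which drives effector programmes in T and NK cells, stood at intensities of 32.8 and 290.4, an 8.85-fold difference. Its other probe set was below the floor on the array labelled untreated and at least 9.98-fold higher on the other. Gata3, the master regulator of Th2 cells, was 4.56-fold higher. Plagl1, a zinc finger factor of an imprinted locus, was 3.38-fold higher by its brighter probe set, which is of a type prone to cross-hybridization, and its other probe set was below the floor on both arrays.

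Among the 10 lower factors was Prdm1, which encodes Blimp-1, a repressor that promotes effector differentiation and Il10 expression in T cells. Its intensity was 189.8 on the array labelled untreated and below the floor on the other, at least 7.89-fold lower. Nfil3 and Id2 were 5.28-fold and 5.27-fold lower, with the dimmest of 3 probe sets of Id2 at least 2.11-fold lower, and the homeobox factor Hlx, a partner of T-bet, was at least 3.07-fold lower. The AP-1 family members Fosl2 and Junb and the related Maff differed by -1.81, -1.01 and -1.01, the nuclear receptor Rora by -1.51, Creb3l2 by -1.49 and the aryl hydrocarbon receptor Ahr by -1.48. The dimmer probe set of Creb3l2 was at least 1.80-fold lower, and short of 2-fold by its measured value. Ahr was close to the floor on the array labelled IL-27-treated. Tbx21, which encodes T-bet and which IL-27 is known to raise, differed by -0.23, Batf by -0.30, Irf1 by 0.34 and Stat3 by -0.40. Bcl6 and Foxp3 were near the floor on both arrays, with intensities of 20.6 and 25.3 for Bcl6 and 16.2 and 24.3 for Foxp3. The median over the 221 factors was -0.05, at percentile 2.83 of random lists, and at percentile 0.09 with the mean of probe sets and 6.43 with dim values raised to the floor. Subtracting each array's median gave 5 higher and 8 lower factors, with Id3 and Rel, named after their values were seen and at 0.96 each before the subtraction, newly past 2-fold and Junb and Maff no longer so.

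**Figure D2:**
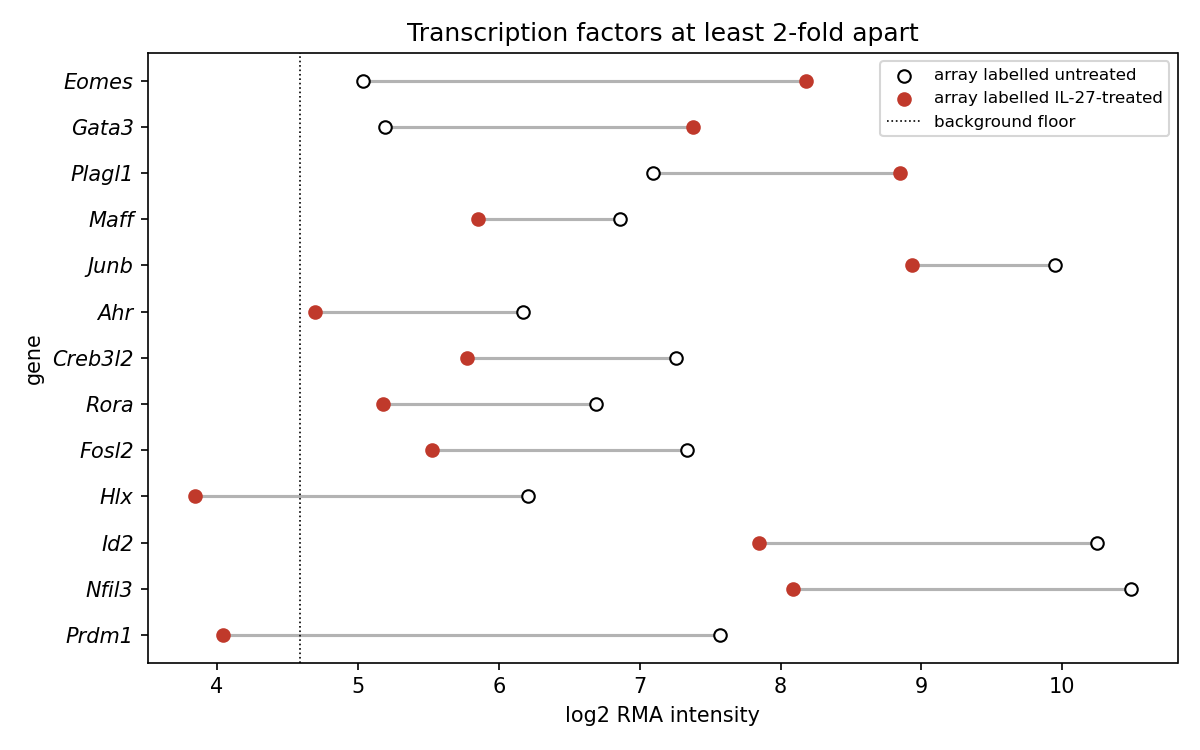
Log2 RMA intensity of the 13 transcription factors at least 2-fold apart, on the array labelled untreated (open circles) and the array labelled IL-27-treated (red circles), joined by a line per gene, with the background floor of 4.59 dotted. Eomes, Gata3 and Plagl1 lie higher on the array labelled IL-27-treated and the other 10 lie lower, with Hlx and Prdm1 below the floor there.

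Genes of the STAT3 response were lower as a group on the array labelled IL-27-treated. Of 18 above background, 7 were at least 2-fold lower by measured values, 6 with dim values raised to the floor, and 0 at least 2-fold higher, and the list's median of -0.61 lay below all 10000 random lists. Socs3, the feedback inhibitor of STAT3 signalling, had intensities of 1122 and 185.8, which is 6.04-fold lower, and Il21, Rora, Ahr and Junb were among the 7. The module of IL-10-producing type 1 regulatory T cells, a cell type that IL-27 is known to favour, had 6 of 15 members at least 2-fold lower, 5 with dim values raised to the floor, and 0 higher, with a median of -0.63, also below all 10000 random lists, and -0.24 at percentile 0.08 when dim genes were kept. Il10 was at least 1.96-fold lower, with an intensity of 47.2 on the array labelled untreated and a value below the floor on the other, and Lag3, an inhibitory receptor of such cells, differed by -1.09. The lists shared 5 members above background, and the 10 members of the module that were not shared had a median of -0.38, at percentile 0.19. That split of the module was made after its values were seen.

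Genes of class I antigen presentation, a pathway that IL-27 is known to raise, lay in the opposite direction. All 14 were within 2-fold, 12 of them on the higher side, with a median of 0.23 at percentile 99.8. The proteasome subunit and activator genes Psmb9, Psmb10 and Psme2 differed by 0.55, 0.45 and 0.49. Tapbp differed by 0.53, and by 0.10 by its dimmer probe set. Socs1, a feedback inhibitor of cytokine signalling, differed by 0.11 and the checkpoint ligand Cd274 by 0.06.

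**Figure D3:**
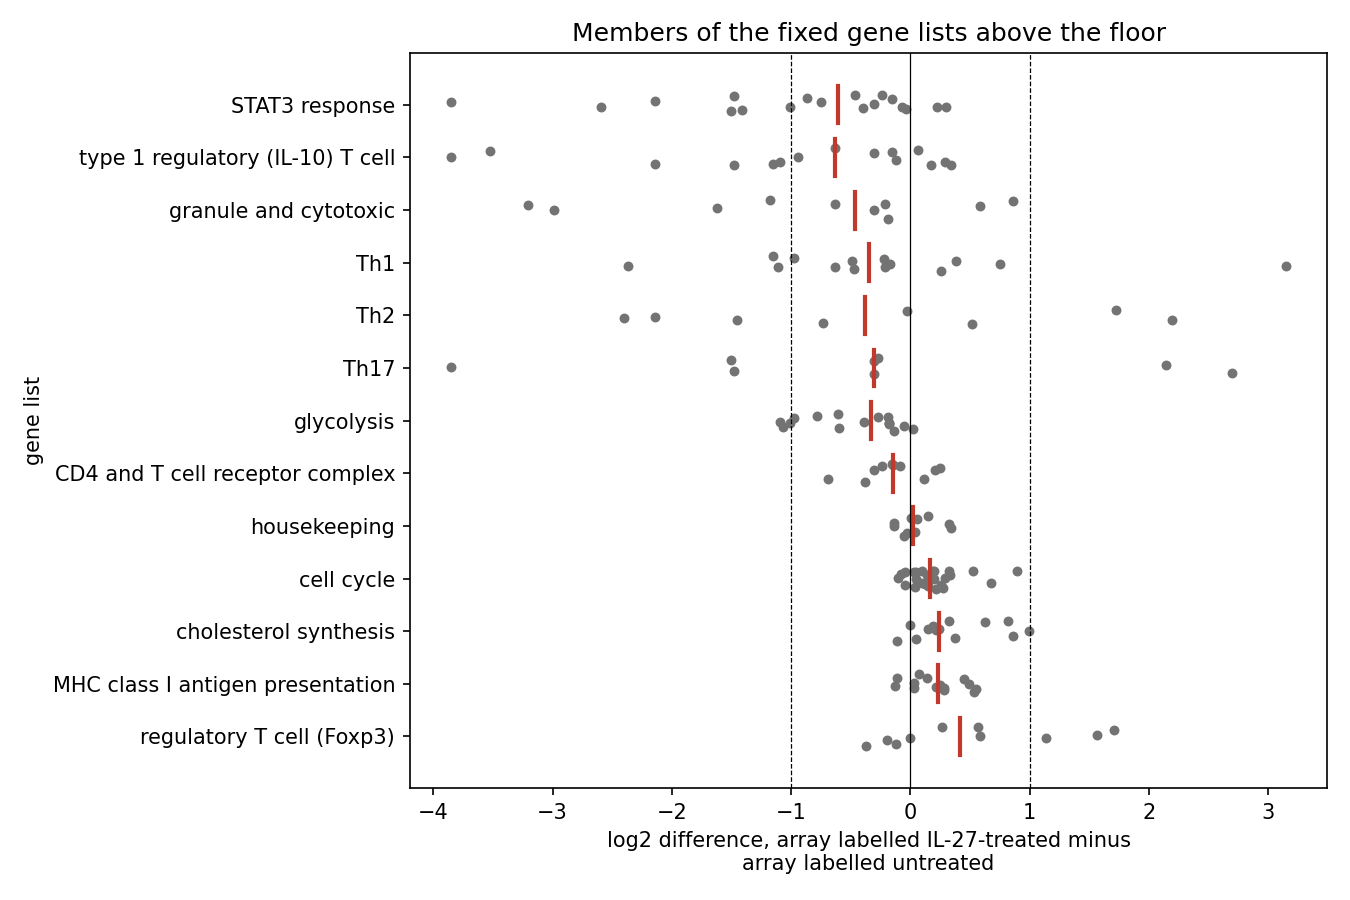
Log2 differences, array labelled IL-27-treated minus array labelled untreated, of the members above background of 13 gene lists fixed beforehand, 1 grey point per gene, with the list's median as a red bar and dashed lines at 2-fold. Among the lists drawn, the lowest medians were -0.63 for the IL-10 module and -0.61 for the STAT3 list. The highest were 0.24 for the cholesterol synthesis list and 0.41 for the Foxp3 list. Not drawn are the dendritic cell and MHC class II list (3 genes, median 0.81) and several lists with medians near 0, such as the activation list. Vertical scatter within a list carries no information.

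Lists of helper T cell lineages held members on both sides. In the Th1 list, Eomes was higher and Hlx, the IL-12 receptor chain Il12rb2 (-1.15) and the chemokine Ccl4 (-1.11) were lower, with a median of -0.35 over 14 genes at percentile 0.06, and -0.22 at percentile 0.61 when dim genes were kept. Ifng differed by 0.75. The Th2 list had Gata3 and the chemokine receptor Ccr8 (at least 2.71-fold) higher and 3 genes lower by measured values, among them Nfil3 and Il10, or 1 with dim values raised to the floor. Its median over 8 genes was -0.38 at percentile 1.48, 0.11 when dim genes were kept and -0.74 with the stricter filter. Il4 was below the floor on both arrays. In the Th17 list, Csf2 and Ccr6 (at least 3.16-fold) were higher and Il21, Rora and Ahr lower, with a median of -0.31 over 8 genes at percentile 2.84. That percentile was 0.69 with dim genes kept and 4.28 with the stricter filter.

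Of 10 genes above background in the Foxp3 regulatory T cell list, 3 were at least 2-fold higher and 0 lower, with a median of 0.41 at percentile 99.98. Nrp1 differed by 1.71 and was close to the floor on the array labelled untreated, at an intensity of 25.2. The cytokine subunit Ebi3, which is also a chain of IL-27, differed by 1.56. The folate receptor family member Izumo1r differed by 1.13, while Ctla4 differed by -0.12. The list was not set apart with dim genes kept (0.10, percentile 90.2), with dim values raised to the floor (0.14, percentile 91.2) or with the mean of probe sets (0.03, percentile 63.3), and its median was 0.27 with the stricter filter. For follicular helper T cells the median was -0.04 over 9 genes (percentile 39.4), with Il21 lower, the adaptor Sh2d1a higher by 1.05, Slamf6 by 0.69 and Pou2af1 at least 1.33-fold lower.

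Secreted cytokines and chemokines differed in both directions, with 8 of 25 genes at least 2-fold higher and 5 lower by measured values, or 3 lower with dim values raised to the floor. Il2 had intensities of 338.0 and 1853, a 5.48-fold difference, and Penk, Tnfsf11 and Csf2 were also among the higher genes, while Tgfb3, Il21, Il10 and Ccl4 were among the lower ones. The list's median was -0.01 (percentile 39.7) and its mean 0.20, so they differ in sign, and the median was 0.077 when dim genes were kept and 0.088 with the mean of probe sets. Among 17 activation genes Il2 and Cd44 (1.17) were at least 2-fold higher, Tnfrsf9 differed by -0.77 and the amino acid transporter gene Slc7a5 by -0.57. The median of that list was -0.004 at percentile 36.3 and its mean 0.14, and with the mean of probe sets the median was -0.14 at percentile 1.74. The 8 inhibitory receptors and ligands had a median of -0.03 (percentile 38.1), with Vsir, which encodes VISTA, at -2.06, Lag3 at -1.09, Entpd1 at least 1.46-fold lower and Cd200 at 0.72.

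In the list of cytokine receptors, JAKs and SOCS genes, 1 of 25 was at least 2-fold higher, Socs2 by 1.14, and Socs3 and Il12rb2 were lower, with a median of -0.11 at percentile 4.63, or 1.26 with the stricter filter and 1.25 with the mean of probe sets. The receptor chains Il27ra and Il6st differed by -0.66 and -0.04, and Jak3 by -0.95. The sign of Il6st turned when each array's median was subtracted. Naive T cell genes had a median of -0.09 over 11 genes (percentile 15.3), with Igfbp4 at -2.33, Bcl2 at -0.97, Klf3 at 0.68 and the egress receptor S1pr1 at least 1.55-fold lower. Among 16 survival and death genes the median was 0.13 (percentile 88.0), or 0.007 at percentile 43.2 with the mean of probe sets, with the death ligand Fasl at 2.11, Casp1 at 0.84 and the caspase-8 regulator Cflar at -1.09. The medians of the follicular helper, activation, inhibitory receptor and cytokine lists, all near 0, turned positive when each array's median was subtracted.

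Cytotoxic granule genes were lower as a group on the array labelled IL-27-treated. Of 10 above background, 4 were at least 2-fold lower by measured values, 3 with dim values raised to the floor, and 0 higher, with a median of -0.47 below all 10000 random lists, and -0.26 at percentile 0.29 when dim genes were kept. Ctsw, a cathepsin of cytotoxic lymphocytes, was 7.94-fold lower and Nkg7 3.08-fold lower. Prf1, which encodes perforin, was at least 6.86-fold lower by its brighter probe set and differed by -0.04 by the other, and Gzma was at least 1.43-fold lower. The other probe set of Prf1 was close to the floor on both arrays, at 4.81 and 4.77 on the log2 scale, and could show little fall. The NK cell receptor genes Klrd1 and Klrk1 were at least 4.75-fold and 2.84-fold lower, while the other 5 genes of the NK and gamma-delta T cell list were below the floor on both arrays.

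Genes of glucose metabolism were lower as a group. Of 16 genes of the glycolysis list, 15 lay on the lower side, 3 of them at least 2-fold, and the median of -0.33 lay below all 10000 random lists. The glucose transporter genes Slc2a3 and Slc2a1 differed by -1.01 and -0.98 and the aldolase gene Aldoc by -1.07. The mitophagy receptor gene Bnip3, which the list also holds though it is not a gene of glycolysis, differed by -1.10. Cholesterol synthesis genes lay on the other side, with 11 of 13 higher by any amount, 0 at least 2-fold, and a median of 0.24 at percentile 98.2. Dhcr7, Idi1, Cyp51 and Nsdhl differed by 0.99, 0.86, 0.81 and 0.62. Of 29 cell cycle genes, 25 were higher by any amount and 0 at least 2-fold, with a median of 0.17 at percentile 98.0. They were led by Tyms (0.89), Ccne2 (0.67), Aurkb (0.53) and Mcm3 (0.33). The other probe set of Aurkb gave 0.085 and that of Mcm3 0.18.

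Markers of CD4+ T cells were within 2-fold. Cd4 differed by 0.21, with its 2 probe sets at 0.21 and -0.16. The 10 genes of a list of Cd4, CD3 chains and other T cell surface and signalling genes were all within 2-fold, with a median of -0.15 at percentile 2.13, Cd5 at -0.69, Zap70 at -0.38, Cd247 at -0.30 and Cd2 at 0.25. That percentile was 4.53 with the mean of probe sets. The 10 housekeeping genes were all within 2-fold, with a median of 0.02 at percentile 50.1 that turned negative after loess normalization. In that list Gusb differed by 0.34, Polr2a by 0.32, Ppia by 0.15 and Ywhaz by -0.14.

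Genes of other cell types were mostly below the floor. Cd8a was below it on both arrays, whereas Cd8b1 had intensities of 119.3 and 176.5, a difference of 0.57. Of the B cell markers 1 of 9 was above background, Cd79b, at most at an intensity of 25.6, close to the floor. The macrophage list had 2 of 12, Cd68 with a difference of -0.99 and Csf1r with -0.11. The granulocyte and mast cell list had 1 of 10, Elane, at most at 24.2, and the stromal list 1 of 6, Pecam1, with intensities of 26.4 and 26.0. Of the 7 erythroid and platelet genes 0 were above it. In the list of dendritic cells and MHC class II, 3 of 10 were above background, with differences of both signs: H2-Ab1 differed by -1.94, Cd74 by 1.56 and H2-Eb1 by 0.81. Their median of 0.81 lay at percentile 99.8, and it was 0.06 at percentile 84.7 when dim genes were kept.

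Several probe sets above background were present for 2263 genes. Among the 82 of these that were at least 2-fold apart, every other probe set had the same direction in 82, and all were at least 2-fold apart in 45. Other probe sets gave -1.18 for Igfbp4, -2.07 for Slc2a3, -1.11 for H2-Ab1, -0.62 for Cflar, 0.89 for Cd44 and 0.25 for Tyms, whose brightest ones are given above. For Serpinb1a, Ahr and Aldoc, as for Plagl1, the other probe set was below the floor on both arrays. The SD of 1 probe set's log2 difference, taken from the brightest 2 of each gene, was 0.20.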

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

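All tests of explanations in this part were chosen after the result was seen. Signals outside the gene comparison appeared in 4 places. Of 2256 probe sets above background without a listed gene, 20 were at least 2-fold higher on the array labelled IL-27-treated and 54 at least 2-fold lower. Of 219 probe sets assigned to several genes, 1 was at least 2-fold higher and 1 lower. The array's own control probe sets for 18S ribosomal RNA were the third. A control probe set at the 3' end of the pyruvate carboxylase transcript, the fourth, was 2.37-fold lower, with intensities of 134.8 and 56.8. The gene's own probe set (Pcx), named after its value was seen, was 2.83-fold lower.

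The 3 control probe sets for 18S ribosomal RNA were 2.93, 2.33 and 2.15-fold higher on the array labelled IL-27-treated, with log2 differences of 1.10 to 1.55 that kept their sign under all 3 other normalizations. A brighter array would raise the hybridization spike-ins as much, but the highest of 18 such probe sets differed by 0.49, with a median of 0.20, which argues against it as the whole cause. Degraded RNA would raise the ratio of 3' to 5' signals, and the highest change of that log2 ratio among the control sets of Actb, Gapdh and Tfrc was 0.014, with -0.36 for Tfrc. These 3 transcripts thus gave no rise beyond the SD of 0.29 for a difference between 2 probe sets. For 18S itself the change was 0.33, barely above that SD. Ribosomal RNA has no poly(A) end for the kit to copy from, so this ratio may not read degradation. Degradation of 18S thus stays open, while the 3 transcripts gave no sign of it. A different carry-over of ribosomal RNA into the labelled material, or a difference between the cultures that goes with IL-27, may lie behind the difference and was not tested.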

How the results depend on the processing

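No paired analysis was possible because there is 1 array per group, and for the same reason no replicate could be left out. Raising dim values to the floor was chosen after seeing the data. Across the 12 alternatives 0 genes were called in the opposite direction. The fold thresholds, the filters on dim probe sets and a rule that every probe set must pass could not turn a direction. A pseudocount of 16 and raising dim values to the floor could not turn a given probe set either. They could only change which probe set represents a gene. The other normalizations shifted named genes by far less than 2-fold, so this 0 says little. Apart from the fold thresholds the counts ran from 73 to 113 higher and 137 to 197 lower. At 1.5-fold, 355 genes were higher and 502 lower, with 14 and 25 transcription factors, and at 3-fold 35 and 70, with 5 lower factors, as the threshold itself sets. Subtracting array medians gave 5 higher factors. Of 949 differences of named genes, 935 kept their side of 2-fold, 11 fell short of it and 3 newly passed it. Among the 935 are 119 under each changed filter on dim probe sets, which leaves a gene's difference as it is. Of those at least 2-fold apart 0 turned, while the small ones of Il6st and Pecam1 changed sign under other normalizations. Of 198 list medians, 178 kept their call. Without the filter on dim genes the Th2 median turned to 0.11, those of the Foxp3 (0.10), Cd4 and T cell receptor (-0.15) and class II (0.063) lists were no longer set apart, and those of Th17 (-0.31) and transcription factors (-0.050) newly were. With the stricter filter the receptor list was set apart (-0.16). Loess set apart Th17 (-0.32) and factors (-0.071), and a pseudocount of 16 Th17 (-0.28). The mean of probe sets set apart Th17 (-0.44), activation (-0.14), receptors (-0.14) and factors (-0.073), and not Foxp3 (0.035) or Cd4 and T cell receptor (-0.12). Without cross-hybridizing types of probe set, factors (-0.068) were and Cd4 and T cell receptor genes (-0.15) were not. With dim values at the floor, Th17 (-0.29) was and Foxp3 (0.14) was not. The cause was not tested. Signal over background limits genes near 24.1 in intensity, where only bounds can be given.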

Other observations

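All tests in this part, and the gene families in its opening paragraphs, were chosen after the values were seen, so the counts and medians describe families picked from these arrays. The directions of the genes and medians named below held under all 3 other normalizations unless stated. Of 10 ligands of the TNF superfamily above background, 4 were at least 2-fold higher on the array labelled IL-27-treated and 6 within 2-fold. The higher ones were Tnfsf11 (3.36), Cd70 (at least 3.96-fold), Fasl (2.11) and Tnfsf8 (1.49), while Tnf differed by -0.22 and Tnfsf9 by -0.80. The 5 immunity-related GTPase genes were all on the higher side, 3 of them at least 2-fold, with a median of 1.04, led by Iigp1 (2.73), Irgm1 (1.18) and Tgtp1 (1.04). Of 5 guanylate-binding protein genes, 0 were at least 2-fold apart, with a median of -0.43, Gbp2 at -0.43 and Gbp10 at 0.64. Both families have close relatives, and cross-hybridization between them was not tested. Of 3 Schlafen genes, 2 were at least 2-fold higher, of which Slfn2 was at 0.97 after loess normalization, and Slfn8 was within 2-fold at 0.59.

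Of Ndrg1 and 4 prolyl hydroxylase genes, 3 were at least 2-fold lower on the array labelled IL-27-treated. Ndrg1 differed by -1.90, Egln3 by -1.44 and P4ha2 by -1.31, while Egln1 and Egln2 were within 2-fold at -0.56 and -0.38. Ndrg1 was added to the family by hand. Of 9 cathepsins, 6 were on the lower side, joined by Ctsc after loess normalization, with a median of -0.39 and Ctsw at -2.99, a gene that the granule list also holds, while Ctss was at 0.55. The 66 cytosolic ribosomal protein genes had a median of 0.005, which turned negative after loess normalization.

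STAT3-response and IL-10-module genes were lower on the array labelled IL-27-treated, against what IL-27 is known to do. An exchange of the 2 arrays' labels may account for these genes, and Il2 (2.45) and Gata3 (2.19), which IL-27 is known to restrain, go with it, as does the class I gene H2-Q10 (-3.86), which is prone to cross-hybridization. It would put the class I antigen presentation list (median 0.23), which IL-27 is known to raise, on the wrong side, while of the interferon-inducible GTPases the immunity-related family (median 1.04) lies with that list and the guanylate-binding proteins (median -0.43) do not. Tbx21, which IL-27 is known to raise, differed by -0.23, near the SD of 0.20 for 1 probe set, and decides little. These genes and lists are not a full tally of known IL-27 targets. Exchanged labels and labels as given thus cannot be told apart with 1 array per group. A late feedback of the cytokine at 60 h, or variation between cultures, also stays open and was not tested.

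Granule genes and the NK receptor genes Klrd1 and Klrk1 were lower together on the array labelled IL-27-treated. More CD8 T cells in the untreated culture could lower them, but Cd8b1 differed by 0.57, the other way, and Cd8a was below the floor on both arrays, so 1 marker decides nothing. More NK cells could do so too, and the highest of 4 NK lineage markers was at 3.89 on the log2 scale on the array labelled untreated, below the floor of 4.59, where a small share of cells would not show. The labels call the cells naive CD4+ T cells, a selection meant to leave out both types. A difference of the CD4+ T cells themselves between the cultures stays open and was not tested.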
